A study of Mus musculus with 32 samples.

How the data were processed

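RNA-seq of sorted mouse HSC and MPP was read from 1 table per library for 24 libraries, and the groups, replicate numbers and sort gates were taken from the labels. Per the submitters' processing notes, reads were handled on the mouse build mm10 with STAR 2.0.4, Subread, featureCounts 1.4.5, HTSeq 0.8.0 and Partek 6.6, listed without the part each played. The labels name a SMARTer Ultra Low kit with 3 to 5 ng of RNA. Each table lists 41388 Ensembl genes, of which 40254 have a symbol. Per the file headers, the deposited Count column holds raw counts per gene, the CPM column counts scaled to the library total and the RPKM column CPM per kilobase of gene length. The deposited CPM and RPKM columns were checked by recomputing them from the deposited counts and gene lengths, and every fit used the counts. For 14573 genes the exons are listed differently in the 2 cohorts, so no test mixed libraries of both.

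Depth, as the sum of counts over genes, was 10473535 to 27232379 per Vav library and 7852483 to 20724168 per Mx1 library. The 12 Vav libraries (4 groups of 3) and the 12 Mx1 libraries (6 groups of 2) were fitted separately in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and quasi-likelihood F tests with robust dispersion estimates gave p-values, adjusted by the Benjamini-Hochberg method with a threshold of 0.05 in each comparison. This left 15818 genes in the Vav fit, with 8 residual degrees of freedom and a biological coefficient of variation of 0.337, and 19616 genes in the Mx1 fit, with 6 degrees of freedom and a coefficient of 0.786. The standard error (SE) of a log2 fold change is its size over the square root of F. Group levels are means and SD of CPM over libraries.

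There were 13 comparisons. In the Vav cohort these were Jarid2-KO against control in HSC and in MPP, the difference between those effects, and control MPP against control HSC. In the Mx1 cohort they were control MPP against control HSC, Jak2V617F against control, the double mutant against Jak2V617F and against control in each cell type, and the differences of the Jak2V617F effect and of the added Jarid2-KO effect between cell types. Sets of 30 gene lists, written before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members, with p adjusted over lists, and again with the correlation estimated for each list. Counts of members past the test use p adjusted over all genes, and counts adjusted over the list alone are named as such. The HSC list holds Mycn and Runx1t1, genes remembered from the published study, so it is not independent of that study. Sets of genes called in 1 cohort were tested by camera in the other. A further list of 20 heart muscle genes was written after heart transcripts were seen, and libraries with more than 4% of their counts in it were set apart by a term in added Mx1 fits.

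The genes named were fixed by rule before the data were examined. Jarid2 and Jak2 come first in every cohort, and Mycn and Runx1t1 are given in every comparison as genes remembered from the published study. Added to these are the 8 largest rises and the 8 largest falls past the threshold with an average logCPM of at least 2 and no overlap between the libraries of both groups, leaving out predicted genes, small RNA genes and unnamed loci, up to 4 members past the threshold of each fixed list, and all genes where fewer than 10 pass. A few genes that the rule names are not reported here, and such a gene was also taken out of the table of results flagged for a closer look, so that table is not the complete output of its rule. Genes named outside the rule were chosen after their values were seen. These are genes shared by both Vav comparisons, genes near Jarid2, list members that did not pass, and Xist, Ddx3y, Ly6a, Mpo, Elane and Fos as markers of single libraries.

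The alternatives were DESeq2 size factors in the edgeR fit, no filter, a stricter filter of 20 counts, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, and the replicate number or the pool as a block. Others were only the groups compared in the fit, leaving out each library in turn, the estimated correlation for lists, and the 200 genes of smallest p as a set. These were chosen before the data were examined. The heart term, fits without genes on chromosome 13 and a block with crossed replicate numbers were added after. Where leaving out a library leaves 1 in a group, that library is assumed to vary like the others. The pipeline was tested on simulated data in 3 simulations with 200 changed genes each. In the Vav layout 75.3% of genes changed by a log2 of 2 and 20.7% of those changed by 1 were found, and 4.22% of calls were unchanged genes. In simulations of the Mx1 comparisons of control MPP with HSC, Jak2V617F with control and double mutant with Jak2V617F, nothing was called without a term for the 2 sets. With it 41.7 to 54.7% and 3 to 8.33% were found, with 5.93 to 15.5% of calls unchanged genes. Without the term, lists given no change passed in the comparisons whose groups hold the sets unequally (a mean of 8.33 to 11 of 30 lists). Each gene was drawn independently, so the simulations do not show how lists behave where genes vary together. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. The 8 samples of ChIP for H3K27me3 were left out, because the files used here hold RNA counts.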

Results

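RNA was sequenced from 2 sorted blood cell populations of C57BL/6 mice in 24 libraries. Per the labels, haematopoietic stem cells (HSC) were lineage-negative, cKit+, Sca1+, CD150+ and CD48-, and multipotent progenitors (MPP) differed from them by lacking CD150. The Vav cohort held 12 libraries from mice of 8 weeks in 4 groups of 3, control and Jarid2-KO HSC and MPP, with deletion by Vav-Cre, a recombinase active across blood cells. The Mx1 cohort held 12 libraries from mice of 10 weeks, 2 months after Mx1-Cre was induced with pIpC, in 6 groups of 2. These were control, Jak2V617F, and Jak2V617F with Jarid2-KO (the double mutant), each as HSC and as MPP. The design text of the series lists an Mx1 group with Jarid2-KO alone where the sample labels give Jak2V617F; the sample labels were followed, and the comparisons with that group rest on them. Jarid2 is an accessory subunit of Polycomb repressive complex 2, which places a repressive mark on histone H3, and Jak2V617F is an activating kinase variant of myeloproliferative disease. Each library came from a pool of mice and the labels present replicates as separate pools, so p-values measure the spread between these pools. Total counts ran from 10473535 to 27232379 per Vav library and from 7852483 to 20724168 per Mx1 library. The 8 other samples of the series, made by ChIP for H3K27me3, were not analysed here.

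Counts of the targeted gene, Jarid2 (ENSMUSG00000038518, mm10 chromosome 13, 44729474 to 44921643), were not lower in the libraries labelled Jarid2-KO. In Vav HSC, Jarid2 stood at 103 ± 36.3 CPM (counts scaled to the library total; mean ± SD, n = 3) in Jarid2-KO and at 93.9 ± 15.8 (n = 3) in control libraries. In Vav MPP the values were 116 ± 11.7 (n = 3) and 109 ± 17.2 (n = 3). In the Mx1 cohort, the means of 2 libraries were 119 in double mutant HSC (68.3 and 169) and 57.5 in Jak2V617F HSC, and 72.9 and 62.5 in the matching MPP, with 56.8 in control HSC and 58.2 in control MPP. The counts add up all exons of a gene, and an allele that lacks a few exons can still be transcribed, so these values do not check the genotype labels. Jak2 (ENSMUSG00000024789, chromosome 19, 29251828 to 29313080) stood at 69.1 ± 7.45 CPM in Jarid2-KO and 64.5 ± 11 in control Vav HSC, and at 69.8 ± 31.4 and 58.7 ± 13.1 in Vav MPP (n = 3 each). In the Mx1 cohort its means of 2 libraries were 26.8 in control, 38.8 in Jak2V617F and 46.1 in double mutant HSC, and 51.8, 42.6 and 53.5 in the matching MPP. Jak2 did not pass the test in any of these comparisons, and counts cannot show its V617F base change.

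The first Vav comparison asked what Jarid2 loss changes in stem cells. Jarid2-KO HSC held more transcripts of the growth factor Igf1, the MYC-family transcription factor Mycn and the STAT5 feedback inhibitor Cish, and fewer transcripts of the interferon-response genes Oas2 and Usp18. Igf1 rose from 27.4 ± 4.61 to 143 ± 27.7 CPM (mean ± SD, n = 3 each; log2 fold change 2.30, SE 0.29, adjusted p = 0.00334). Mycn (ENSMUSG00000037169, chromosome 12, 12936096 to 12941914) rose from 115 ± 6.86 to 257 ± 33.2 CPM (log2 1.09, SE 0.21, adjusted p = 0.039). Oas2, an antiviral nucleotide synthetase, fell from 28.2 ± 11.8 to 5.58 ± 2.3 CPM (log2 -2.42, SE 0.40, adjusted p = 0.0193). Of 15818 genes tested, 90 passed, 40 higher and 50 lower in Jarid2-KO HSC. Among the largest rises were Dsp, a desmosome protein encoded near Jarid2 (log2 4.66, SE 0.52), the secreted glutathione peroxidase Gpx3 (4.03, SE 0.55), the death-domain receptor Tnfrsf25 (2.61, SE 0.51), Gkn3 (2.31, SE 0.46) and the kinase Pim2 (2.10, SE 0.41). Among the largest falls were the lipid-cleaving enzyme gene Gdpd3 (log2 -4.25, SE 0.81), the vesicle protein gene Syt9 (-3.92, SE 0.71), the cyclin-dependent kinase inhibitor Cdkn2c (-2.61, SE 0.39), the innate immune kinase Alpk1 (-2.60, SE 0.49) and the chemokine Ccl3 (-2.50, SE 0.30). Ear6 (4.76), Eif5al3-ps (2.80) and Rps3a3 (-5.84) also passed, but each has near-identical copies elsewhere in the genome, and their counts are uncertain. The count of 90 fell to 47, 22 and 15 without control HSC replicates 1, 2 and 3, and to 16, 14 and 26 without Jarid2-KO HSC replicates 1, 2 and 3. It was 690 by DESeq2, 1419 by limma-voom, 828 with no filter on low counts and 293 when only these 6 libraries were fitted.

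Of the 30 gene lists, 12 passed in Jarid2-KO HSC, 9 upward and 3 downward, and none kept its call with an estimated correlation between genes (lowest adjusted p = 0.191). The interferon response list had 4 of 30 members lower (Oas2, Ifit3 and Usp18 among them), 0 higher and 26 not past the test, with a median log2 fold change of -0.65 (camera adjusted p = 1.21e-09, and adjusted p = 0.245 with an estimated correlation). Adjusted over the list alone, 14 members were lower and 1 higher. Usp18, a feedback regulator of the pathway, fell by 1.02 on the log2 scale (SE 0.20). The STAT5 target list had 3 of 14 members higher, Id1 (3.18, SE 0.65), Pim2 and Cish (1.56, SE 0.25), and 0 lower, with a median of 0.63 (adjusted p = 7.08e-05, and adjusted p = 0.191 with an estimated correlation). In the macrophage and dendritic cell list 2 of 15 members were lower, the antigen-presentation genes H2-Aa (-1.36, SE 0.22) and Cd74 (-1.32, SE 0.22), at a list median of -0.20 (adjusted p = 0.00547, and adjusted p = 0.338 with an estimated correlation). The granulocyte-monocyte list, markers of another lineage, had a median of 1.07 with 0 of 19 members past the test over all genes and 10 higher when adjusted over the list alone (adjusted p = 2.84e-08, and adjusted p = 0.245 with an estimated correlation). The HSC list itself had 1 of 36 members higher (Mycn), 0 lower and a median of 0.09 (adjusted p = 0.223, and adjusted p = 0.697 with an estimated correlation). Runx1t1, a corepressor gene of that list, had a log2 fold change of 0.04 (SE 0.23, adjusted p = 0.939).

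**Figure D1:**
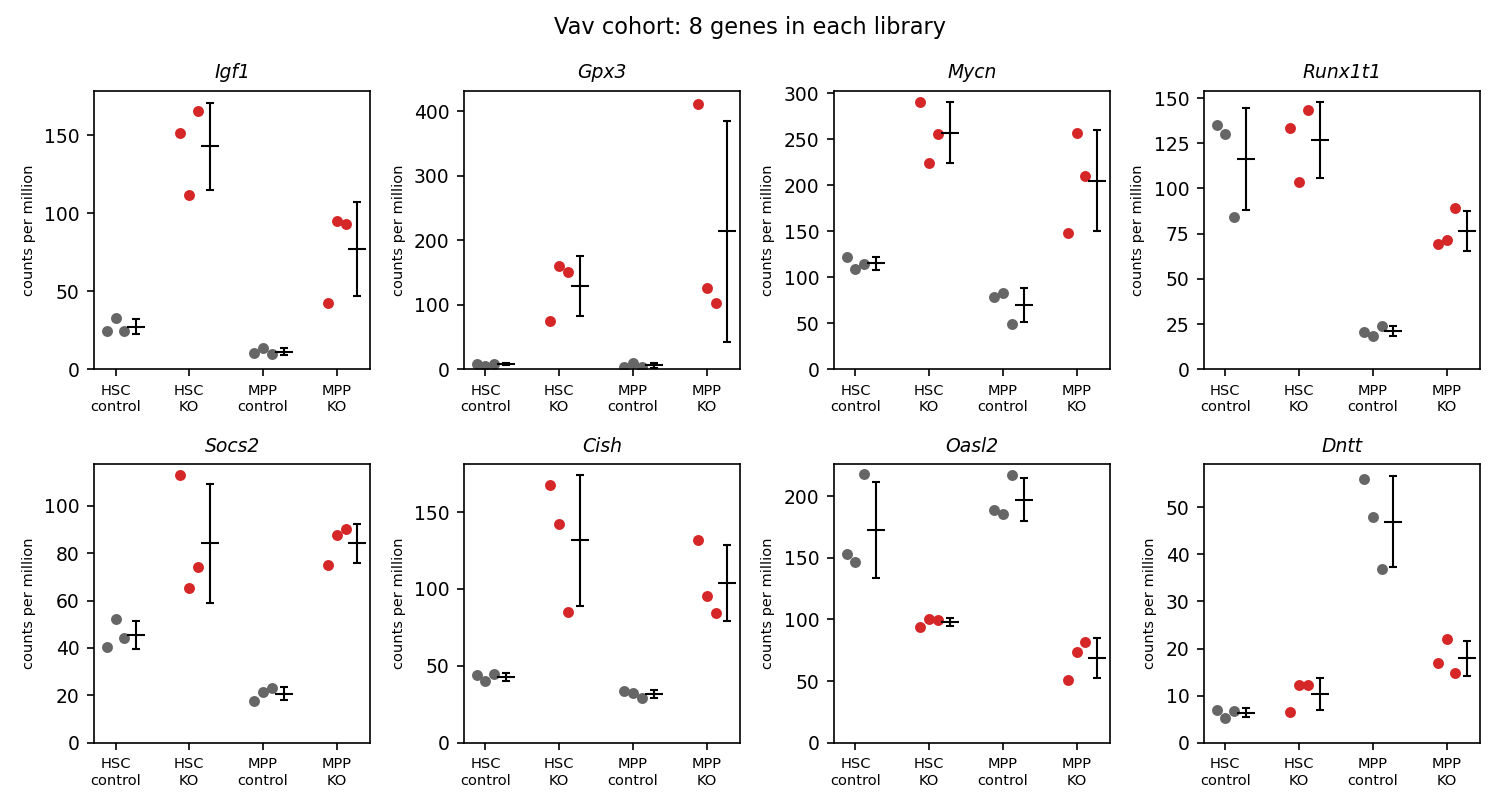
CPM of Cish, Dntt, Gpx3, Igf1, Mycn, Oasl2, Runx1t1 and Socs2 (vertical axes) in each Vav library by group, with 3 points per group and the mean ± SD beside them. Runx1t1 averages 20.9 in control MPP and 76.6 in Jarid2-KO MPP, against 116 and 127 in the HSC groups.

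The second Vav comparison asked the same of multipotent progenitors. Jarid2-KO MPP had higher levels of the stem cell genes Mycn, Runx1t1 and Socs2 than control MPP, and lower levels of the lymphoid genes Dntt, Satb1 and Il12a and of the interferon-response gene Oasl2. Runx1t1 (ENSMUSG00000006586, chromosome 4, 13743436 to 13893649) rose from 20.9 ± 2.77 to 76.6 ± 11 CPM (mean ± SD, n = 3 each; log2 1.87, SE 0.24, adjusted p = 0.00214). Mycn rose from 70 ± 18.2 to 205 ± 54.6 CPM (log2 1.55, SE 0.22, adjusted p = 0.00365). Socs2, a cytokine feedback inhibitor, rose from 20.7 ± 2.79 to 84.2 ± 8.24 CPM (log2 2.02, SE 0.24, adjusted p = 0.00144). Oasl2 fell from 197 ± 17.3 to 68.8 ± 16.2 CPM (log2 -1.52, SE 0.20, adjusted p = 0.00289). In all, 150 of 15818 genes passed, 81 higher and 69 lower. That split was 722 and 387 by DESeq2, 918 and 388 with no filter, 267 and 194 by limma-voom, and 88 and 72 with the stricter filter. Large rises included Gpx3 (log2 5.21, SE 0.58), the matricellular protein gene Ccn3 (4.19, SE 0.83), Dsp (4.01, SE 0.50), Tnfrsf25 (3.81, SE 0.55), the actin-bundling protein gene Fscn1 (3.46, SE 0.52) and the growth factor Pdgfc (3.29, SE 0.48). Large falls included Syt9 (-5.65, SE 0.82), Lrrc66 (-4.03, SE 0.76), Gdpd3 (-3.56, SE 0.79), the zinc finger gene Zfp429 on chromosome 13 (-3.55, SE 0.69), Phf11d (-2.87, SE 0.46), Ccl3 (-2.39, SE 0.28) and the melanocortin receptor gene Mc5r (-2.37, SE 0.33). Ifi211 (4.63), Ifi204 (4.12) and Rps3a3 (-5.51) belong to families of near-identical copies, and their counts are uncertain.

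Among the lists in Jarid2-KO MPP, 18 of 30 passed, 13 upward and 5 downward, and none kept its call with an estimated correlation (lowest adjusted p = 0.0517). The interferon response list had 5 of 30 members lower, 0 higher and 25 not past the test (median -0.76, adjusted p = 1.21e-17, and adjusted p = 0.0517 with an estimated correlation). Adjusted over the list alone, 18 were lower. Ifi27l2a (-2.96, SE 0.51), Oas2 (-1.82, SE 0.39) and Ifit3 (-1.63, SE 0.32) were among them. The HSC list had 3 of 36 members higher, Socs2, Runx1t1 and Mycn, and 0 lower (median 0.24, adjusted p = 0.00281, and adjusted p = 0.259 with an estimated correlation). Runx1t1 and Mycn were remembered from the published study, so their calls are not independent support for this list. Without Jarid2-KO MPP replicates 2 and 3 the list lost its call, at medians of 0.03 and 0.24. Adjusted over the list alone, 8 were higher and 1 lower. Other members of that list, such as the stem cell regulators Mecom (-0.14), Hlf (-0.36) and Procr (-0.01), did not pass. The lymphoid-primed list had 3 of 20 members lower, Dntt, a DNA polymerase of antigen receptor assembly (-1.38, SE 0.28), the chromatin organiser Satb1 (-1.34, SE 0.28) and the cytokine subunit Il12a (-1.03, SE 0.21), and 0 higher (median -0.44, adjusted p = 0.000502, and adjusted p = 0.0517 with an estimated correlation). The fetal HSC list had 2 of 10 members higher, the RNA-binding protein genes Igf2bp3 (2.26, SE 0.46) and Igf2bp2 (1.91, SE 0.32), at a median of 0.90 (adjusted p = 0.00118, and adjusted p = 0.116 with an estimated correlation). In the STAT5 target list, Socs2 and Cish (1.72, SE 0.25) were higher among 14 members and 0 lower (median 0.86, adjusted p = 0.00021, and adjusted p = 0.0517 with an estimated correlation). The macrophage and dendritic cell list had 3 of 15 members lower, Cd68 (-1.36, SE 0.23), H2-Aa (-1.03, SE 0.21) and Cd74 (-1.01, SE 0.22), at a median of -0.56 (adjusted p = 0.00128, and adjusted p = 0.261 with an estimated correlation), and lost its call without Jarid2-KO MPP replicate 3 (-0.49). The 12 PRC2 subunits had 0 members past the edgeR test at 0.05 adjusted over all genes, at a median of -0.01 against an upward camera direction (adjusted p = 0.91, and adjusted p = 0.965 with an estimated correlation); 1 was higher when adjusted over the list alone.

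Jarid2-KO MPP replicate 1 stood apart from the other Vav libraries. It held 4881 CPM of the granule gene Mpo and 7104 of Elane, against 1050 to 1954 of Mpo and 1534 to 3012 of Elane in the other 2 Jarid2-KO MPP libraries and 879 to 1438 and 648 to 1026 in control MPP, and 0.559% of its counts were mitochondrial, the lowest of the Vav libraries. Its level of Xist, a transcript of female cells, was 1.82 CPM against 266 to 336 in the other 5 Vav MPP libraries, while the protocol text describes pools of both sexes. S100a8 stood at 754 to 1660 CPM in Jarid2-KO and 373 to 514 in control MPP. The granulocyte-monocyte list had a median of 0.54 in Jarid2-KO MPP (adjusted p = 0.003, and adjusted p = 0.406 with an estimated correlation), with 0 of 19 members past the test and 4 higher when adjusted over the list alone, and it lost its call without replicate 1 (median 0.36, adjusted p = 0.102). The stroma and endothelium list, with Cxcl12 (log2 4.35, SE 0.97) and Col4a1 (1.49, SE 0.27) higher among 13 members, had a median of 1.98 with that library (adjusted p = 0.00021, and adjusted p = 0.142 with an estimated correlation) and 1.30 without it. The immediate early list, markers of cell stress in handling, had a median of 1.64 with it (adjusted p = 1.3e-05, and adjusted p = 0.261 with an estimated correlation) and 0.62 without it. The count of 150 genes was 155 without Jarid2-KO MPP replicate 1, with 108 genes shared by both, so part of the calls depends on that library. The count was 39, 55 and 34 without control MPP replicates 1, 2 and 3, and 1512 without Jarid2-KO MPP replicate 3. It was 1109 by DESeq2, 461 by limma-voom, 1306 with no filter and 19 when only these 6 libraries were fitted.

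**Figure D2:**
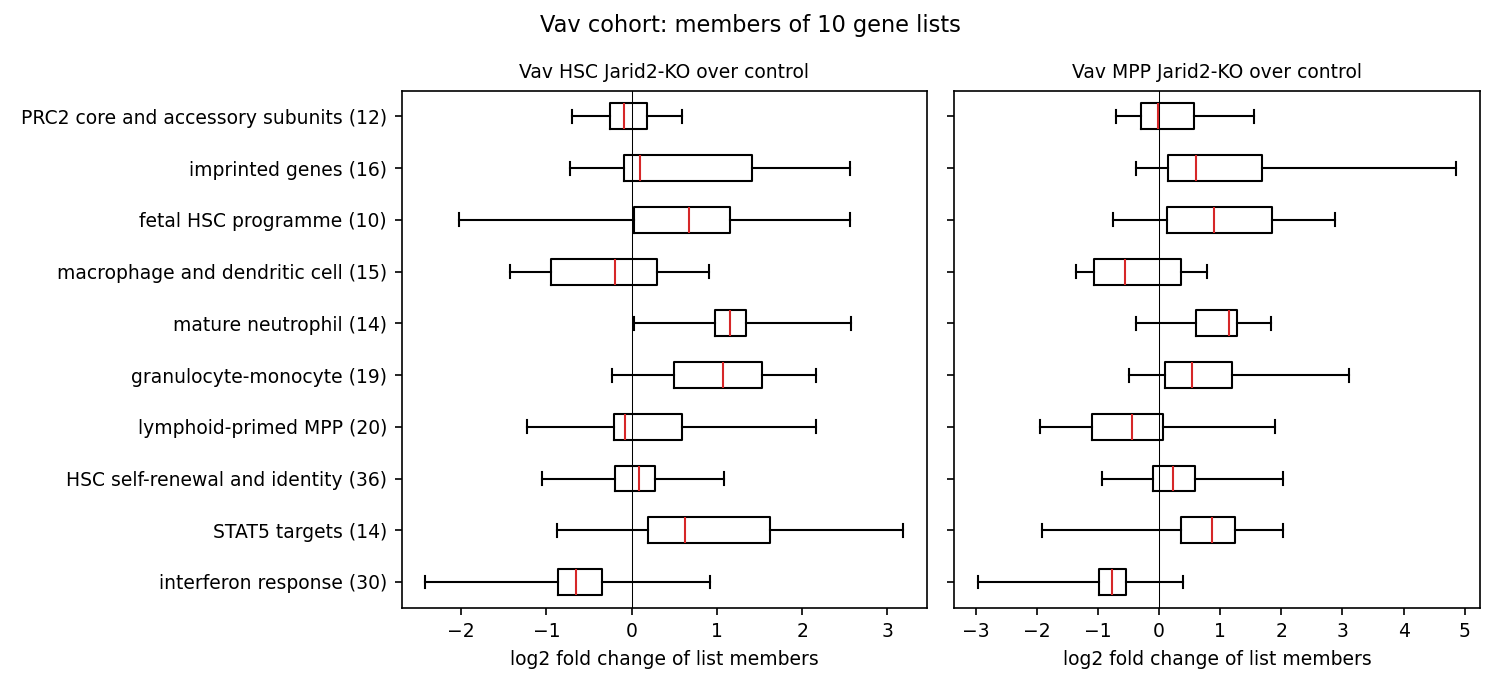
Box plots of the log2 fold changes of the members of 10 gene lists (horizontal axis) in Jarid2-KO over control HSC and MPP of the Vav cohort, with whiskers to the extremes and medians in red. The median of the interferon response list lies at -0.65 in HSC and -0.76 in MPP, and that of the STAT5 target list at 0.63 and 0.86.

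The third Vav comparison asked whether the effect of Jarid2 loss differed between MPP and HSC. No gene passed the edgeR test of that difference among 15818, with 419 genes at an unadjusted p under 0.05, 7 calls by DESeq2 and 0 by limma-voom. The difference for Runx1t1 was 1.83 on the log2 scale (SE 0.33, adjusted p = 0.704) and for Mycn 0.46 (SE 0.30, adjusted p = 1). The calls of both cell types, from separate libraries that may share pools of mice, overlapped. Of the 40 genes higher in HSC and 81 higher in MPP, 22 were shared where independent lists would share 0.205, and of the 50 and 69 lower genes 24 were shared where 0.218 would be. Residuals of HSC and MPP with the same genotype and number had a median correlation of 0.0822 (highest 0.299), so independence of the lists is not shown. Shared higher genes included Igf1 (2.30 in HSC, 2.76 in MPP), the neuron-derived factor gene Ndnf (2.05, 3.02), the protease inhibitor Timp3 (1.42, 2.07), Cish (1.56, 1.72) and Mycn. Shared lower genes included Oas2, Ifit3, the surface peptidase Dpp4 (-1.43, -1.79), Cdkn2c (-2.61, -2.06), H2-Aa and Cd74. No gene was called in opposite directions, and across all genes tested the fold changes of both cell types correlated with a Spearman rho of 0.623, genes not being independent replicates.

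**Figure D3:**
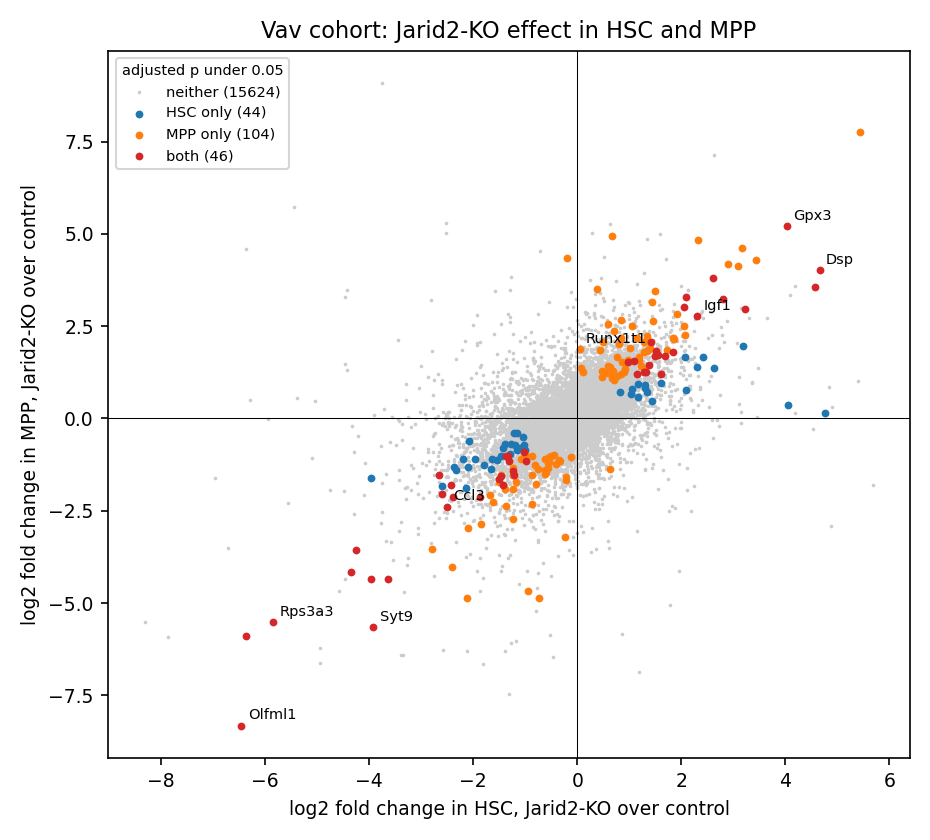
Log2 fold change of Jarid2-KO against control in Vav HSC (horizontal axis) and Vav MPP (vertical axis), 1 point per gene tested, with genes past the test in HSC, in MPP or in both in colour. The 46 genes called in both lie in the lower left and upper right quadrants, 24 lower and 22 higher.

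Control cells of the Vav cohort show how the 2 sorted populations differ. Control MPP had higher levels of the cytokine receptor Flt3 and of lymphoid genes than control HSC, and lower levels of Slamf1, the CD150 gene by which the cells were sorted, and of platelet-lineage genes. Flt3 rose from 47.2 ± 21.1 CPM in HSC to 491 ± 87.9 in MPP (mean ± SD, n = 3 each; log2 3.33, SE 0.38, adjusted p = 0.000419). Slamf1 fell from 62.5 ± 4.57 to 4.38 ± 0.902 (log2 -3.90, SE 0.46, adjusted p = 0.000461). In this comparison 185 of 15818 genes passed, 81 higher and 104 lower in MPP. Higher genes included Sema3d (4.76, SE 0.87), Wfdc17 (4.26, SE 0.53), the lymphocyte gene Tespa1 (3.17, SE 0.29) and Ccl3 (3.03, SE 0.29). Lower genes included Gkn3 (-5.08, SE 0.59), the caveola component Cavin2 (-4.83, SE 0.49), the chaperone Clu (-4.56, SE 0.39) and Cyp26b1, which degrades retinoic acid (-3.52, SE 0.62). The eosinophil ribonucleases Ear6 (5.08), Ear1 (4.92) and Ear2 (3.72) share sequence, and their counts are uncertain. The lymphoid-primed list had 8 of 20 members higher and 0 lower, among them Dntt (2.81, SE 0.29), Cd52 (1.99, SE 0.38) and Satb1 (1.91, SE 0.28), at a median of 1.54 (adjusted p = 6.56e-05 with an estimated correlation). The HSC list had 9 of 36 members lower and 0 higher, with Runx1t1 at -2.54 (SE 0.25), Vwf, the platelet adhesion factor, at -2.51 (SE 0.23) and Clec1a at -2.26 (SE 0.33) (adjusted p = 0.00297 with an estimated correlation), while Mycn, at -0.79 (SE 0.21, adjusted p = 0.118), did not pass. The megakaryocyte-platelet list had 8 of 19 members lower, such as Treml1 (-2.52, SE 0.53), Itgb3 (-1.67, SE 0.35) and Mmrn1 (-1.46, SE 0.28), and 1 higher, Thbs1 (1.49, SE 0.29) (median -1.12, adjusted p = 0.00297 with an estimated correlation). Of the imprinted genes, 3 of 16 were lower, including the growth inhibitors Cdkn1c (-1.80, SE 0.36) and Grb10 (-1.18, SE 0.22) (median -1.06, adjusted p = 0.00297 with an estimated correlation). In all, 14 lists passed and 6 of these kept their call with an estimated correlation. The count of 185 was 97, 70 and 102 without control HSC replicates 1, 2 and 3, and 64, 61 and 69 without control MPP replicates 1, 2 and 3. It was 474 by DESeq2, 735 by limma-voom, 451 with no filter and 395 with only these 6 libraries.

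The Mx1 libraries carried transcripts of heart muscle. A list of 20 heart muscle genes, among them the sarcomere genes Ttn and Myh6, took 0.537 to 1.24% of the counts in 6 libraries and 6.24 to 9.52% in the other 6, against at most 0.00331% in the Vav libraries. The high libraries were control MPP replicate 2, Jak2V617F HSC replicate 2, both Jak2V617F MPP libraries, and replicate 1 of double mutant HSC and of double mutant MPP. They also held more mitochondrial counts, 4.96 to 6.74% against 1.31 to 1.94%, more of the Y-linked transcript Ddx3y, 78.5 to 116 against 7.24 to 16.6 CPM, and less Xist, 137 to 202 against 306 to 510 CPM. Genes of blood cells were lower too, with Ptprc at 96.9 to 226 against 313 to 461 CPM and Kit at 150 to 370 against 390 to 1121. The 20 genes thus do not give the whole share of heart RNA, and CPM values are not directly comparable between high and low libraries. The 12 libraries thus fall into 2 sets. Of the 6 groups, 4 hold 1 library of each set, both control HSC libraries are low and both Jak2V617F MPP libraries are high. The comparisons were run as designed, and again with the set as a term of the model, a choice made after the heart transcripts were seen. The term assumes the same fold between the sets in every group, and calls made with it rest on that. The assumption does not hold for every gene. Ly6a stood at 48.4 CPM in the high and 7.05 in the low Jak2V617F HSC library, but at 78.2 and 150 in double mutant HSC.

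**Figure D4:**
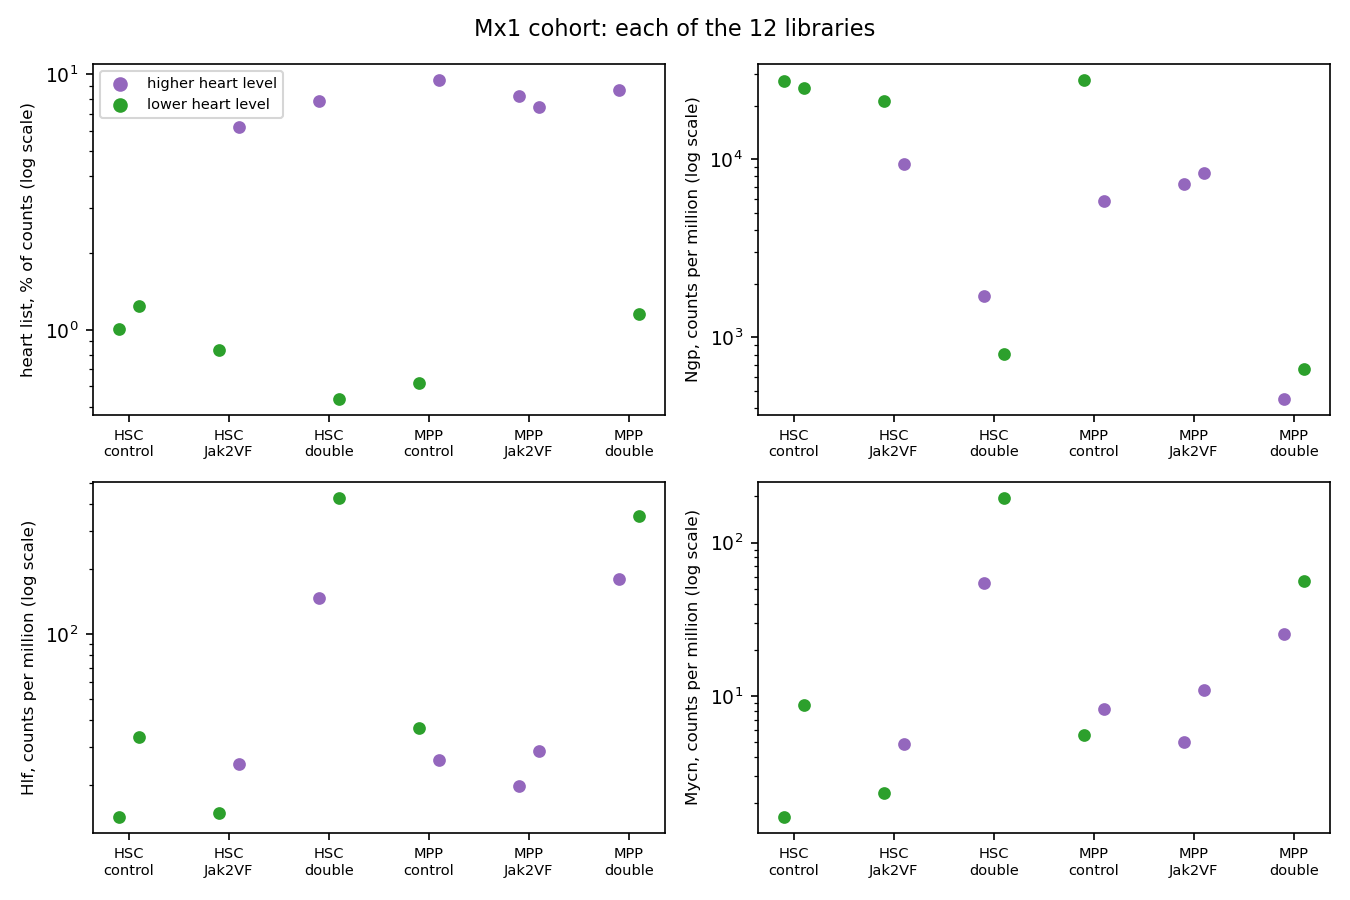
Percent of counts from the heart muscle list, and CPM of Ngp, Hlf and Mycn, in each of the 12 Mx1 libraries by group, on logarithmic vertical axes with the higher heart level in purple and the lower in green. The heart list takes 0.537 to 1.24% in 6 libraries and 6.24 to 9.52% in the other 6.

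Without Jarid2 loss, the Mx1 comparisons gave no gene past the test. Control MPP and control HSC differed at 0 of 19616 genes by edgeR, with 523 at an unadjusted p under 0.05, 3 calls by DESeq2 and 0 by limma-voom. Slamf1 stood at 0.196 and 5.21 CPM in the control HSC replicates and at 6.95 and 3.77 in the control MPP replicates, against means of 62.5 and 4.38 in the Vav cohort. Cd48, the gene of a marker absent from both sort gates, stood at 122 and 133 CPM in control HSC and at 127 and 37.4 in control MPP replicates 1 and 2, against means of 10.3 and 34.6 in the Vav cohort. The granule gene Ngp stood at 27373 and 25186 in HSC and at 27938 and 5842 in MPP, against 635 and 1133. Control MPP replicate 2 is the only high-heart library of these 4, and without it the gap in Cd48 and Ngp between the 2 cell types is not seen. The cohorts were not tested against each other. Jak2V617F HSC against control HSC gave 0 genes by edgeR (299 at an unadjusted p under 0.05, 5 by DESeq2, 0 by limma-voom), and Jak2V617F MPP against control MPP also gave 0 (264 unadjusted, 0 by DESeq2, 0 by limma-voom). With the set term edgeR gave 0 in each as well, with 1113, 1581 and 585 genes at an unadjusted p under 0.05. Among the lists, the erythroid one had a median of 0.38 in Jak2V617F MPP (adjusted p = 0.0253, and adjusted p = 0.783 with an estimated correlation) and 1.11 with the set term (adjusted p = 9.81e-10, and adjusted p = 0.912 with an estimated correlation), where 4 of 22 members were higher when adjusted over the list alone. The granulocyte-monocyte list had a median of -0.89 in Jak2V617F HSC (adjusted p = 1.19e-06, and adjusted p = 0.913 with an estimated correlation) and -0.92 in Jak2V617F MPP (adjusted p = 3.79e-05, and adjusted p = 0.783 with an estimated correlation). With the set term these were -0.58 and -0.47, and without control MPP replicate 1 the median in MPP turned to 0.31. In simulations of these 3 comparisons edgeR found 0 of the genes changed by a log2 of 2 without the term, and with it 45.7% between control cells, 46% in Jak2V617F HSC and 41.7% in Jak2V617F MPP. Of 30 simulated lists, a mean of 11, 8.33 and 8.33 that had been given no change passed without the term, and 0.333 each with it. The simulations drew each gene independently, so they cannot show that list tests hold their error rate where genes vary together. In other splits of the real Vav libraries, which mix the real groups, up to 9, 11 and 10 lists passed, against 0 unchanged lists in the Vav simulation.

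Double mutant HSC were compared with Jak2V617F HSC to see what Jarid2 loss adds to the kinase variant. Double mutant HSC had more transcripts of stem cell genes, such as Mycn, Hlf and Runx1t1, and fewer of granulocyte genes such as S100a8 and Elane, and the libraries compared also differed in genes of the sort gate. Slamf1 stood at 30.8 and 124 CPM in double mutant, 12.7 and 5.04 in Jak2V617F and 0.196 and 5.21 in Mx1 control HSC replicates 1 and 2, and Cd48 at means of 17, 108 and 128 (n = 2 each). Vav control HSC averaged 62.5 CPM for Slamf1, 10.3 for Cd48 and 666 for Hlf. A difference in the cells collected and an effect of Jarid2 loss cannot be told apart here. The gene calls came with the set as a term. As designed, edgeR called 0 genes (919 at an unadjusted p under 0.05, 345 by DESeq2, 5 by limma-voom). With the term, 539 of 19616 genes passed, 187 higher and 352 lower. Hlf stood at a mean of 287 CPM in double mutant (147 and 427 in replicates 1 and 2) and 20 in Jak2V617F HSC (14.9 and 25) (log2 3.38, SE 0.42, n = 2 each, adjusted p = 3.94e-05 by edgeR) and Mycn at 125 (54.7 and 196) and 3.61 (2.35 and 4.87) (4.67, SE 0.82, adjusted p = 0.00934). S100a8, a calcium-binding protein of neutrophils, stood at 322 and 3959 CPM (log2 -3.84, SE 0.36, adjusted p = 2.64e-08). The HSC list had 18 of 36 members higher and 0 lower, Runx1t1 among them (3.72, SE 0.72), at a median of 2.32 (adjusted p = 3.44e-41, and adjusted p = 0.0711 with an estimated correlation). In the mature neutrophil list 6 of 15 members were lower, with S100a9 at -3.87 (SE 0.43), Chil3 at -3.86 (SE 0.66) and Wfdc21 at -3.93 (SE 0.45) (median -3.84, adjusted p = 0.0711 with an estimated correlation). The granulocyte-monocyte list had 7 of 19 lower, with Cebpe, a transcription factor of granule formation (-3.60, SE 0.67), Ms4a3 (-3.59, SE 0.66) and Elane (-3.22, SE 0.60) (median -2.81, adjusted p = 0.0801 with an estimated correlation). The mitosis list had 14 of 22 lower, such as the proliferation marker Mki67 (-1.71, SE 0.31) and Birc5 (-1.74, SE 0.33) (median -1.27, adjusted p = 0.0944 with an estimated correlation).

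Other groups moved in the same comparison of double mutant with Jak2V617F HSC, under the same limit on the cells collected. The megakaryocyte-platelet list had 7 of 21 members higher, including the calcium channel Trpc6 (4.95, SE 0.84), Mmrn1 (4.28, SE 0.41) and Selp (2.69, SE 0.52), and 0 lower (median 1.70, adjusted p = 0.0711 with an estimated correlation). The erythroid list had 5 of 22 lower, among them the red cell transcription factors Klf1 (-3.13, SE 0.62) and Gata1 (-1.89, SE 0.32), and 0 higher (median -1.96, adjusted p = 0.117 with an estimated correlation). Of the interferon-response genes 4 of 30 were higher, Ifi44 (3.32, SE 0.55), Oasl2 (2.66, SE 0.41), Gbp2 (2.55, SE 0.41) and Gbp7 (1.42, SE 0.30), and 0 were lower (median 0.92, adjusted p = 0.0711 with an estimated correlation); the median of that list in Vav Jarid2-KO HSC was -0.65, and the difference between cohorts was not tested. Of the STAT5 targets, 3 of 14 were higher, Socs2 (1.96, SE 0.50), Pim1 (1.39, SE 0.31) and Bcl2l1 (1.38, SE 0.35) (median 0.84, adjusted p = 0.0711 with an estimated correlation). Of the Hox genes, Hoxa10 (3.85, SE 0.83) and Hoxa9 (2.67, SE 0.62) were higher among 20 (median 2.31, adjusted p = 0.0801 with an estimated correlation). Cd48 fell by 2.91 on the log2 scale (SE 0.37). Within the low-heart set, where each group has 1 library, the HSC list had a median log2 ratio of 3.28 and the neutrophil list of -4.59. Within the high-heart set these were 1.23 and -2.55. The count of 539 was 844 without Jak2V617F HSC replicate 2, 1162 and 289 without double mutant HSC replicates 1 and 2, and 1136 by DESeq2 with the term.

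Double mutant MPP were compared with Jak2V617F MPP in the same way. As designed edgeR called 0 genes (588 at an unadjusted p under 0.05, 80 by DESeq2, 12 by limma-voom); with the set term it called 116 of 19616, 32 higher and 84 lower. In the HSC list 4 of 36 members were higher, among them Pdzk1ip1 (3.15, SE 0.46), Hlf (3.01, SE 0.43) and the homeobox gene Meis1 (1.52, SE 0.35), and 0 lower (median 0.83, adjusted p = 4.93e-18, and adjusted p = 0.208 with an estimated correlation). Mycn (2.00, SE 0.78, adjusted p = 0.634) and Runx1t1 (2.64, SE 0.71, adjusted p = 0.0914) did not pass. The mature neutrophil list had 4 of 15 lower, including S100a9 (-3.72, SE 0.43) and S100a8 (-3.54, SE 0.37) (median -3.93, adjusted p = 0.143 with an estimated correlation), and Cebpe (-3.75, SE 0.74) and the surface protease Adam8 (-5.75, SE 0.75) also fell. Gbp2 (2.46, SE 0.43), Rtp4 (2.23, SE 0.51) and Oasl2 (2.20, SE 0.42) of the interferon list were higher, 3 of 30 (median 0.99, adjusted p = 0.143 with an estimated correlation), as were Mndal (2.58, SE 0.34), Tgtp2 (2.54, SE 0.42), Cd74 (2.38, SE 0.43) and H2-Aa (2.00, SE 0.35). The erythroid list had a median of 0.52 with 0 of 22 members past the test (adjusted p = 0.00366, and adjusted p = 0.69 with an estimated correlation), and the megakaryocyte-platelet list a median of -0.60 with 1 of 21 higher and 1 lower (adjusted p = 0.193); in HSC these medians were -1.96 and 1.70. Both Jak2V617F MPP libraries lie in the high-heart set and double mutant MPP replicate 2 does not. Ngp stood at 7223 and 8361 CPM in Jak2V617F MPP and at 452 and 665 in double mutant MPP, against a mean of 1133 in Vav control MPP. Hlf stood at 19.9 and 28.9, 180 and 353, and 1027 in the same order, while mean Cd48 was 51.1 in Jak2V617F and 47.1 in double mutant MPP. A difference in the cells collected and an effect of Jarid2 loss cannot be told apart here. The count of 116 was 207 and 187 without Jak2V617F MPP replicates 1 and 2, 269 and 256 without double mutant MPP replicates 1 and 2, and 335 by DESeq2 with the term.

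The double mutants were also compared with control cells. In HSC, edgeR called 0 genes as designed (1249 at an unadjusted p under 0.05, 437 by DESeq2, 97 by limma-voom) and 459 with the set term, 186 higher and 273 lower. These libraries also differed in genes of the sort gate. Slamf1 stood at 30.8 and 124 CPM in double mutant and 0.196 and 5.21 in control HSC, and Cd48 at means of 17 and 128. A difference in the cells collected and an effect of genotype cannot be told apart here. The HSC list had 13 of 36 members higher, with Mycn at 4.37 (SE 0.80), Runx1t1 at 2.56 (SE 0.68, adjusted p = 0.0327), Clec1a at 3.67 (SE 0.80) and Hlf at 3.43 (SE 0.42) among them, and 0 lower (median 1.87, adjusted p = 0.0957 with an estimated correlation). The interferon list had 7 of 30 higher, such as Oasl2 (3.82, SE 0.44) and Ifit1 (3.34, SE 0.66) (median 1.31, adjusted p = 0.0957 with an estimated correlation), and Socs2 (2.41, SE 0.52) and Cish (2.29, SE 0.53) of the STAT5 targets were higher too. S100a8 (-4.25, SE 0.39) and Camp (-4.39, SE 0.76) fell with 4 other neutrophil genes of 15. In MPP, edgeR called 0 genes as designed (924 unadjusted, 234 by DESeq2, 0 by limma-voom) and 309 with the term, 122 higher and 187 lower. Ngp stood at 452 and 665 CPM in double mutant and at 27938 and 5842 in control MPP replicates 1 and 2, so the same limit holds for MPP. There the HSC list had 6 of 36 higher, Runx1t1 among them (2.79, SE 0.68, adjusted p = 0.0222) (median 1.20, adjusted p = 0.303 with an estimated correlation), while Mycn, at 2.28 (SE 0.74, adjusted p = 0.225), did not pass. The haem-pathway gene Blvrb (2.18, SE 0.33) and the carbonic anhydrase Car2 (1.61, SE 0.33), 2 of 22 erythroid members, were also higher (median 1.64, adjusted p = 0.373 with an estimated correlation), and the chemokine receptor Cxcr2 (-4.22, SE 0.77) was lower. Replicates differed in erythroid genes, with Gata1 at 55.9 and 411 CPM in double mutant and 179 and 39.7 in control MPP replicates 1 and 2. The count of 459 was 1638 without control HSC replicate 2 and 1345 and 211 without double mutant HSC replicates 1 and 2. That of 309 was 1042 without control MPP replicate 2 and 593 without double mutant MPP replicate 1.

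Gene sets called in the Vav cohort were tested in the Mx1 double mutants. The 40 genes raised in Vav Jarid2-KO HSC had a median log2 fold change of 1.02 in double mutant against Jak2V617F HSC, with 85% above 0 (camera adjusted p = 2.65e-08, and adjusted p = 0.0572 with an estimated correlation), and 1.07 with the set term (adjusted p = 1.11e-09, and adjusted p = 0.0189 with an estimated correlation). As designed, its median was 0.46, 0.46 and 0.26 with the call lost when the set was drawn without Vav control HSC replicates 1, 2 and 3, and 0.26 and 0.21 without Jarid2-KO HSC replicates 1 and 2. The 49 tested genes lowered in Vav Jarid2-KO HSC were also higher there, with a median of 0.65 (adjusted p = 3.08e-05, and adjusted p = 0.0635 with an estimated correlation), and 0.51 with the set term (adjusted p = 2.74e-05, and adjusted p = 0.0666 with an estimated correlation). That call was lost without Vav control HSC replicates 1 and 2 (0.21 and 0.90) and without Jarid2-KO HSC replicates 1, 2 and 3 (0.10, 0.25 and -0.47). The raised and the lowered set thus both rose, in libraries that also differed in Slamf1 and Cd48, genes of the sort gate. A rise of the raised set there does not show a shared effect of Jarid2 loss. In MPP, the genes raised in Vav Jarid2-KO MPP had a median of -0.12 against an upward camera direction (adjusted p = 0.547, and adjusted p = 0.839 with an estimated correlation) and 0.45 with the set term (adjusted p = 0.000332, and adjusted p = 0.331 with an estimated correlation). Those lowered had a median of 0.23 (adjusted p = 0.0985, and adjusted p = 0.597 with an estimated correlation) and 0.05 with the term (adjusted p = 0.96). Genes higher in Vav control HSC than MPP had a median of -0.14 in double mutant MPP, against an upward direction (adjusted p = 0.547), and genes higher in MPP a median of -0.21 (adjusted p = 0.198). With the set term these were 0.30 (adjusted p = 0.0142, and adjusted p = 0.419 with an estimated correlation) and -0.46 (adjusted p = 2.74e-05, and adjusted p = 0.356 with an estimated correlation). The reverse sets, from Mx1 control cells, were empty because no gene passed there. As for the difference between cell types, edgeR called 0 genes for the Jak2V617F effect (299 unadjusted, 1 by DESeq2, 0 by limma-voom) and 0 for the added Jarid2-KO effect (479 unadjusted, 21 by DESeq2, 0 by limma-voom). For that effect Mycn had a difference of -2.56 (SE 1.12, adjusted p = 1) and Runx1t1 of -1.23 (SE 1.36, adjusted p = 1). With the set term 3 genes passed for the added effect, and these counts were 47 and 158 without Jak2V617F HSC replicates 1 and 2, 40 and 36 without Jak2V617F MPP replicates 1 and 2, 244 and 32 without double mutant HSC replicates 1 and 2, and 106 and 44 without double mutant MPP replicates 1 and 2.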

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

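The tests of linked genes in the Mx1 cohort and all counts of other splits were chosen before their results were seen; the odds ratios near Jarid2, the tests of the heart transcripts and the tests of the double mutant HSC were chosen only after.

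The added effect of Jarid2-KO on Jak2V617F cells differed between MPP and HSC for 3 genes by a test of the difference in edgeR with the heart term. Among them were the haem-pathway gene Blvrb (log2 difference 3.14, SE 0.49, adjusted p = 0.00397, n = 2 per group) and the surface glycoprotein gene Cd24a (2.78, SE 0.48, adjusted p = 0.0123). With the heart term, 1 gene passed under the stricter filter and 2 with DESeq2 size factors, so Blvrb and Cd24a did not both keep their call under the stricter filter. Blvrb was lower in double mutant than in Jak2V617F HSC (-2.31) and stood at 0.82 in MPP, where it did not pass the test. The erythroid list had medians of -1.96 in HSC and 0.52 in MPP (adjusted p = 0.117 and 0.69 with an estimated correlation), and replicates differed: Hba-a1, Gata1 and Car1 were at 917, 411 and 1344 CPM in double mutant MPP replicate 2 against 194, 55.9 and 187 in replicate 1, and Gata1 and Car1 at 445 and 3787 in Jak2V617F HSC replicate 1 against 116 and 1057 in replicate 2. The DESeq2 test of a difference between cell types called 7 genes for the Vav Jarid2-KO effect, 1 for the Jak2V617F effect and 21 for the added Jarid2-KO effect, where edgeR without the heart term called 0 in each (419, 299 and 479 genes at an unadjusted p under 0.05).

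Genes called in the Vav cohort were more frequent within 25 Mb of Jarid2 on chromosome 13 than elsewhere. In HSC, 7 of 313 genes near Jarid2 and 83 of 15504 others passed (odds ratio 4.25, 95% interval 1.64 to 9.26, Fisher exact p = 0.00204), and in MPP 9 of 313 and 141 of 15504 (3.23, 1.43 to 6.38, exact p = 0.00301). The window was chosen after the cluster was seen, neighbouring genes are not independent, and Ssr1, Dsp, Fbp1 and Zfp367 passed in both cell types. The lower bound of 1.43 therefore does not decide against a response that ignores position. DNA of another strain linked to the Jarid2 allele may explain part of the cluster, as may an effect of the allele on its neighbours, which was not tested. Of 12 such genes, 8, or 66.7%, kept their direction in the Mx1 double mutants in HSC and 66.7% in MPP, too few to tell. Zfp367 was higher in all 4 comparisons (1.69 in Vav MPP, 1.85 and 1.93 in Mx1 HSC and MPP), while Dsp, at 4.66 and 4.01 in Vav, was at -0.31 and 0.36 in Mx1.

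Heart muscle transcripts stood at 2 levels in the Mx1 libraries, with medians of 0.920 and 8.03% of the counts. The parts of the list held by the 15 of 20 genes with at least 1% of it varied little over the 12 libraries (median CV 2.61%; 5.00 to 6.34% for 4 of the others and 34.0% for Nppa, at 0.03% of the list), which is consistent with a single source of heart RNA added in different amounts. The levels did not follow genotype or cell type, since 4 of 6 groups hold both. Mixing before sequencing and reads of other libraries assigned by index remain open. Median Ddx3y was 10.6 CPM in the low and 92.2 in the high libraries, following the heart share. Median Xist was 341 and 161 CPM, and median Ptprc, a gene of blood cells, 387 and 145. Ddx3y can thus come with the heart RNA. Whether the pools also differed in sex balance cannot be read from these values.

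As designed, edgeR called 0 genes between Mx1 double mutant and Jak2V617F HSC. With the heart term, part of the HSC list was higher and part of the granulocyte-monocyte list lower in double mutant HSC, but neither list passed with an estimated correlation. The median log2 ratio of the HSC list was 3.28 within the low level and 1.23 within the high level, with 1 library per group in each. The level of heart transcripts alone thus does not set the direction of the HSC list. The size of the ratio differed between the levels, and single libraries give no spread for it. A smaller share of neutrophil precursors alone would raise other lineages alike, but 3 of 4 lists of other lineages had a median below -1 (erythroid -1.96, lymphoid-primed -1.24) while the megakaryocyte-platelet list was at 1.70. Log2 ratios within the low and the high level were 3.24 and 2.50 for Slamf1, the CD150 gene, and -2.58 and -2.71 for Cd48. Cells outside the CD150 and CD48 gates in the Jak2V617F libraries could give these ratios, while a part played by Jarid2 loss stays open. In Vav HSC, mean Slamf1 was 62.5 CPM in control and 87.8 in Jarid2-KO, and mean Cd48 10.3 and 24.6. Cd48 was thus not lower in Vav HSC without Jarid2. For the Sca1 gate, cells outside it and an effect of Jarid2 loss cannot be told apart. The ratio of Ly6a, its gene, was 4.31 within the low level and 0.69 within the high level. Ly6a itself differed between the levels, which leaves the ratio within the high level hard to read. It stood at 7.05 CPM in the low and 48.4 in the high Jak2V617F HSC library, and at 6.71 and 63.4 in control MPP. In double mutant HSC it went the other way, at 150 and 78.2. Mx1 control HSC, with Slamf1 at 0.196 and 5.21, Cd48 at 122 and 133 and Ngp at 27373 and 25186 CPM, were on the side of the Jak2V617F libraries. Vav control HSC, also with Jarid2 intact, had means of 62.5, 10.3 and 635 CPM. These levels argue against Jarid2 loss as the only source of the Slamf1 and Cd48 ratios. The cohorts were not tested against each other.

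For 3 Vav libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 90 genes in HSC, 150 in MPP and 185 between control cells, and the highest of the other splits gave 0 each time, so 1 of 10 was as large. For lists the real splits gave 12, 18 and 14 and the highest others 9, 11 and 10. For the Vav difference edgeR called 0 genes (419 at an unadjusted p under 0.05, 7 by DESeq2, 0 by limma-voom), and since no split can give fewer, the 100 splits drawn, of which the highest gave 3, say nothing about chance.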

How the results depend on the processing

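Alternatives with the heart term, with crossed replicate numbers or without genes on chromosome 13 were chosen only after the data were seen. The causes of the changes below were not tested, except that fits without a library or with only the groups compared have fewer libraries, and fits with no filter test more genes.

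Counts of genes past the test moved by more than 1.5 times under these settings. In Vav HSC (90) there were 828 with no filter, 690 by DESeq2, 1419 by limma-voom, 45 with replicate number as a block (42 of them shared), 293 with only the groups compared, and 14 to 47 without 1 library (47, 22 and 15 without control HSC replicates 1, 2 and 3, and 16, 14 and 26 without Jarid2-KO HSC replicates 1, 2 and 3). In Vav MPP (150) these were 1306, 1109, 461 and, with only the groups compared, 19, and 34 to 1512 without 1 library (39, 55 and 34 without control MPP replicates 1, 2 and 3, and 1512 without Jarid2-KO MPP replicate 3). Between Vav control cells (185) they were 451, 474, 735 and 395, and 61 to 102 without 1 library (97, 70 and 102 without control HSC replicates 1, 2 and 3, and 64, 61 and 69 without control MPP replicates 1, 2 and 3). The Vav difference, with 0 genes by edgeR (419 at an unadjusted p under 0.05, 0 by limma-voom), gave 74 with no filter and 7 by DESeq2. DESeq2 size factors in the edgeR fit gave 90, 150 and 187, and the stricter filter 104, 160 and 190.

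The Mx1 comparisons had 0 genes by edgeR. With no filter and by DESeq2, control MPP against HSC gave 5 and 3 (523 at an unadjusted p under 0.05), Jak2V617F HSC 11 and 5, with 6 in a fit of only the groups compared (299), and Jak2V617F MPP 2 and 0 (264). Double mutant against Jak2V617F HSC (919) gave 258 and 345, 5 by limma-voom, 539 with the heart term, 27 with crossed numbers as a replicate block, and 0 to 8 without 1 library (8 without double mutant HSC replicate 1). In MPP (588) this was 85, 80, 12 by limma-voom and 116 with the heart term. Double mutant against control HSC (1249) gave 320 and 437, 97 by limma-voom, 383 with only the groups compared, 459 with the heart term, 207 with the crossed block, and 0 to 69 without 1 library (69 without double mutant HSC replicate 1). In MPP (924) it gave 189, 234, 309 with the heart term, 51 with the crossed block, and 0 to 129 (129 without control MPP replicate 2). The Jak2V617F difference (299) gave 6 and 1, and the added Jarid2-KO difference (479) gave 35, 21, 3 with the heart term, and 0 to 2 (2 without double mutant MPP replicate 1). Residuals of libraries with the same number had a median correlation of -0.0261 in Vav and 0.0267 in Mx1, and those of HSC and MPP with the same genotype and number 0.0822 and 0.0448.

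With the heart term, DESeq2 gave 1136 for double mutant against Jak2V617F HSC (539), and leaving out 1 library 289 to 1162 (844 without Jak2V617F HSC replicate 2, and 1162 and 289 without double mutant HSC replicates 1 and 2). In MPP (116) these were 335 and 187 to 269 (207 and 187 without Jak2V617F MPP replicates 1 and 2, 269 and 256 without double mutant MPP replicates 1 and 2). Against control HSC (459) they were 1278 and 211 to 1638 (1638 without control HSC replicate 2, 1345 and 211 without double mutant HSC replicates 1 and 2), and against control MPP (309) 795 and 237 to 1042 (1042 without control MPP replicate 2, 593 without double mutant MPP replicate 1). The added difference (3) gave 1 with the stricter filter, 46 by DESeq2 and 32 to 244 (47 and 158 without Jak2V617F HSC replicates 1 and 2, 40 and 36 without Jak2V617F MPP replicates 1 and 2, 244 and 32 without double mutant HSC replicates 1 and 2, 106 and 44 without double mutant MPP replicates 1 and 2).

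Of gene lists past the test, an estimated correlation left 0 of 12 in Vav HSC, 0 of 18 in Vav MPP and 6 of 14 between Vav control cells. In the Mx1 cohort it left 0 of 10 between control cells, 0 of 4 in Jak2V617F HSC, 0 of 10 in Jak2V617F MPP, 6 of 16 and 0 of 9 for the double mutant against Jak2V617F in HSC and MPP, and 0 of 16 and 0 of 9 against control. The heart term gave 4 between control cells, 9 in Jak2V617F HSC and 4 in Jak2V617F MPP. Without 1 library the counts were 3 to 17 between control cells (17 and 3 without control MPP replicates 1 and 2), 2 to 12 in Jak2V617F HSC (2 without either control HSC library, 12 without Jak2V617F HSC replicate 1). They were 4 to 14 in Jak2V617F MPP (4 without control MPP replicate 1, 6 without Jak2V617F MPP replicate 1), 7 to 16 for double mutant against Jak2V617F MPP (16 without double mutant MPP replicate 1) and 9 to 17 against control MPP (17 without control MPP replicate 2, 15 without double mutant MPP replicate 2).

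Sets from Vav cells tested in double mutant against Jak2V617F cells changed as follows; with the heart term and an estimated correlation together, genes raised in Jarid2-KO HSC passed (1.07) and the others did not (0.51 for those lowered). Genes higher in control HSC (median -0.14) were at 0.30 with the heart term and -0.60 to 0.16 without 1 library (-0.60 and 0.16 without double mutant MPP replicates 1 and 2). Genes higher in control MPP (-0.21) were at -0.46 with the term and -0.33 to 0.027 without 1 library (0.027 and -0.33 without Vav control HSC replicates 2 and 3, -0.08 without Vav control MPP replicate 2, -0.10 and -0.33 without double mutant MPP replicates 1 and 2). Genes raised in Jarid2-KO MPP (-0.12) were at -0.32 as the top 200, 0.45 with the term and -0.62 to 0.22 (0.04 and 0.22 without Vav control MPP replicates 1 and 2, -0.22 without Jarid2-KO MPP replicate 3, -0.62 and 0.19 without double mutant MPP replicates 1 and 2). Genes lowered there (0.23) were at 0.32 as the top 200 and -0.18 to 0.87 without 1 library (0.28 without Jarid2-KO MPP replicate 3, 0.33 without double mutant MPP replicate 1). Genes raised in Jarid2-KO HSC kept a median of 1.02 with an estimated correlation but lost the call, and were at 0.29 as the top 200 and 0.21 to 1.88 without 1 library (0.46, 0.46 and 0.26 without control HSC replicates 1, 2 and 3, 0.26 and 0.21 without Jarid2-KO HSC replicates 1 and 2). Genes lowered in Jarid2-KO HSC stayed at 0.65 with an estimated correlation and lost the call, and were at -0.47 to 1.10 without 1 library (0.21 and 0.90 without control HSC replicates 1 and 2, 0.10, 0.25 and -0.47 without Jarid2-KO HSC replicates 1, 2 and 3). The 4 sets from Mx1 control cells held 0 called genes. As the top 200, genes higher in Mx1 control HSC were at -0.23 in Vav Jarid2-KO MPP (adjusted p = 0.00666) and -0.20 in HSC (adjusted p = 0.0727), and genes higher in Mx1 control MPP at 0.23 and 0.20 (adjusted p = 0.082 each).

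List medians reversed, or their test did, in Mx1 cells. Leaving out control MPP replicate 2 did so for the granulocyte-monocyte list in Mx1 control MPP vs HSC (-0.69, range -2.10 to -0.0665), and in the same comparison for S phase (-0.51, -1.79 to 0.14, and -0.0090 with the heart term), mitosis (-0.48, -1.75 to 0.20, term -0.059), developmental transcription factors (1.72, -0.98 to 2.34, term -0.59) and MYC targets (-0.42, -1.46 to 0.079, term -0.11). In Jak2V617F HSC the neutrophil list (-0.40, -0.99 to -0.17) did so without Jak2V617F HSC replicate 2. In Jak2V617F MPP, leaving out control MPP replicate 1 did so for lymphoid-primed (-0.65, -1.30 to 0.31), granulocyte-monocyte (-0.92, -1.54 to 0.31), stroma (0.70, -0.22 to 3.37, term -0.070), S phase (-0.67, -1.27 to 0.59, term 0.38), mitosis (-0.68, -1.30 to 0.50, term 0.39). The same library did so for developmental transcription factors (0.60, -0.12 to 3.37, term -0.069), imprinted genes (0.52, -0.18 to 3.18) and MYC targets (-0.62, -1.14 to 0.53, term 0.25). In double mutant against Jak2V617F MPP, leaving out double mutant MPP replicate 2 did so for S phase (0.92, -0.36 to 1.62, term -0.17) and developmental transcription factors (-0.62, -2.60 to 0.062, term 0.15).

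Mycn and Runx1t1 turned direction only where they did not pass the test. Runx1t1 in Vav HSC (0.04) ranged from -0.17 to 0.19 without 1 library (-0.17 and -0.02 without replicate 3 of control and of Jarid2-KO HSC). Between Mx1 control cells Mycn (0.41) ranged from -0.25 to 1.90 (-0.25 without control HSC replicate 1) and Runx1t1 (0.21) from -1.08 to 0.96 (-0.01 without control HSC replicate 1, -1.08 without control MPP replicate 2), with -0.29 by limma-voom, -0.046 with the pool as a block and -0.78 with the heart term. Mycn in Mx1 HSC Jak2V617F vs control (-0.56) ranged from -1.25 to 0.89 (0.89 without control HSC replicate 2) and Runx1t1 there (-0.01) from -2.25 to 0.84 (0.33 without control HSC replicate 2, 0.84 without Jak2V617F HSC replicate 1). In Jak2V617F MPP Mycn (0.11) was -0.046 with the number as a block and ranged from -0.54 to 0.55 (-0.08 without control MPP replicate 1, -0.54 without Jak2V617F MPP replicate 2). Runx1t1 in Mx1 MPP Jak2V617F vs control (0.59) ranged from -0.12 to 1.92 (-0.12 without control MPP replicate 1). In the Jak2V617F difference Mycn (0.67) ranged from -0.78 to 1.37 (-0.78 without control HSC replicate 2) and Runx1t1 (0.60) from -0.26 to 2.83 (-0.11 without control MPP replicate 1, -0.26 without Jak2V617F HSC replicate 1). Of 101 named genes past the test without the term, 99 stayed past it with DESeq2 size factors, 101 by DESeq2, 94 by limma-voom, 72 with only the groups compared, 72 with the replicate number as a block and 101 with the stricter filter. Without 1 library, 8 to 10 of 25 stayed past it without 1 Jarid2-KO HSC library, 30 to 42 of 63 without 1 control HSC library, 38 to 39 of 76 without 1 control MPP library and 27 to 38 of 38 without 1 Jarid2-KO MPP library. Of 207 named with the heart term, 0 passed without it, 204 did with DESeq2 size factors, 207 by DESeq2 and 189 with the stricter filter. Without replicates 1 and 2 in turn, 47 and 54 of 55 stayed past the test for control HSC, 31 and 49 of 53 for control MPP, 50 and 58 of 66 for Jak2V617F HSC, 31 and 33 of 36 for Jak2V617F MPP, 118 and 70 of 121 for double mutant HSC and 77 and 66 of 89 for double mutant MPP. None of these turned direction. Of all tests of single genes under the alternatives, 2567 kept direction and side of the threshold, 718 lost the call, 19 gained it and 18 reversed. For single lists these were 761, 200, 0 and 27.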

Other observations

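The 2 tests of double mutant gene sets were chosen before their results were seen, and the fit without Jarid2-KO MPP replicate 1 was planned, but its use as a test of the HSC list was chosen only after.

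Interferon-inducible genes of the Ifi200 family went both ways in Jarid2-KO MPP, with Ifi204 (4.12) and Ifi211 (4.63) higher and Ifi206 (-4.16) and Ifi213 (-5.89) lower; these genes are close copies, and shared reads make their counts uncertain. Antigen-presentation genes H2-Aa and Cd74 were lower in Vav Jarid2-KO cells (H2-Aa -1.36 in HSC and -1.03 in MPP), whereas in Mx1 double mutant MPP with the heart term H2-Aa was at 2.00 and Cd74 at 2.38 against Jak2V617F MPP. Imprinted genes had 2 of 16 members higher in Vav Jarid2-KO MPP and a list median of 0.61 (adjusted p = 0.00021, and adjusted p = 0.0517 with an estimated correlation).

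A hypothesis was that Jarid2-KO MPP take on part of an HSC programme. The tests run do not decide it. They used the 200 genes higher in Mx1 double mutant HSC than MPP and the 200 higher in MPP, but 18 and 28 genes passed in that comparison, and both groups carry Jarid2-KO, so that genes which its loss brings to the HSC level in MPP drop out. In Vav Jarid2-KO MPP these sets had medians of 0.03 and 0.25, both upward (camera p = 0.772 and 0.574 with an estimated correlation, and 0.664 and 0.0425 at the preset correlation). The fixed HSC list holds Mycn and Runx1t1, which were remembered from the published study, so it is not independent of that study. With 3 of 36 members higher in Vav Jarid2-KO MPP and its call lost with an estimated correlation (adjusted p = 0.259), its median was 0.24, and 0.18 without Jarid2-KO MPP replicate 1. Without replicates 2 and 3 it was 0.03 and 0.24 and the call was lost.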
